A study of Homo sapiens with 6 samples.

How the data were processed

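RNA was sequenced from 6 libraries labelled as RPMI-8226, a human multiple myeloma cell line, all at 48 h, with 3 control libraries and 3 libraries of cells treated with the compound XYA1353. The groups and replicate numbers were taken from the sample titles, in which the compound has a code name that the series description equates with XYA1353. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy kit and libraries were made with a SMARTer mRNA kit. The labels used here give no dose, and nothing in them says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

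The deposited values were TPM, a transcript abundance scaled by length and to the same total in each library, computed by the authors per gene in a single table with a column per library. A further pair of deposited columns held the authors' group means and were not used. The table had 61206 rows, of which 60623 carried a human Ensembl gene identifier with a name and 583 were assembled loci without a gene name. The submitters' processing notes name the mouse build GRCm38 (mm10), yet the table held 0 mouse identifiers. The build was therefore not taken from those notes, and the aligner, the counter and the annotation are not given in the sources used here. Of the 60623 identifiers, 60295 were found in a table of human gene names and 58516 in the GENCODE release used here, from which the GRCh38 coordinates in the text were taken by identifier. A symbol was repeated on 1213 rows, and 33609 named rows were listed at 0 in every library. TPM values carry no record of sequencing depth, so the depth per library is unknown, and no counting interval or detection limit can be given. Because a 0 in such a table can also be a failed estimate, a gene is described as listed at 0, not as absent. Whether counting used the strand is not known, so values of overlapping, antisense and near-identical genes are uncertain.

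Genes with a name and a mean of at least 1 TPM over the 6 libraries entered the test, 13392 in all. Values were transformed as log2(TPM + 1) and fitted with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3, with no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no fold threshold. Fold changes are on the log2(TPM + 1) scale, XYA1353 minus control, which understates the change of genes with low values. Errors are standard deviations (SD) of TPM over 3 libraries, or standard errors (SE) of the log2 fold change. Tables were read with pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

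Before the data were examined, the test, the alternatives, 23 gene lists and the rule for naming genes were fixed. Lists with at least 5 tested members, 22 of the 23, were tested against all other genes with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists. The same test with an estimated correlation, and the rotation test fry, were run as alternatives. With an estimated correlation camera called 0 of the 22 lists, with 0 at an unadjusted p under 0.05 and a lowest unadjusted p of 0.101, while fry called 12. The count of called members is given for adjustment over all genes tested and adjusted over the list alone. The genes named were the 6 called genes with the largest change in each direction with a mean of at least 5 TPM and no overlap between groups, and in each list the 2 called members with the largest change and a mean of at least 5 TPM. Where a list had no such member, the tested member with the largest change was taken. For the NF-kB target list the rule took 6 members, and the NF-kB subunit genes and NFKBIA were named whatever their values. Some genes are not reported here, among them some that the rule takes. Genes named outside this rule are said to have been chosen after their values were seen. After the data were examined, 3 lists were added (erythroid, megakaryocyte and B lineage genes), with a list of 23 mRNAs known for a 5' terminal oligopyrimidine tract.

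The alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 5 TPM, a fold threshold of 1 on the log2 scale, median-of-ratios scaling, quantile normalization, rescaling without mitochondrial, immunoglobulin and ribosomal RNA genes, eBayes without a trend, the replicate number as a block, and leaving out each library in turn. A fit with the unnamed loci kept and a fit without both libraries numbered 1 were added after the data were examined. A fit with fewer libraries detects less, so a call lost there need not rest on the library left out. Libraries with the same replicate number deviated from their group means together, with correlations across genes of 0.111, 0.114 and 0.133 for numbers 1, 2 and 3, while the pairs with different numbers lay between -0.116 and -0.002. Deviations from a group mean cancel within the group, so the negative values follow in part from the positive ones and are no separate contrast. The numbers may pair the libraries, and were used only in the alternative fit with a block. This reading comes from these values only, since the labels do not say what a number marks.

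The test was run on simulated values for the same 13392 genes, of which 200 were changed by known amounts. The changed genes were drawn from those above about 5 TPM. On these values the test recovered 4.5% of simulated changes of 0.25 on the log2 scale, 28.4% of changes of 0.5 and 68.2% of changes of 1. Of the calls on simulated data, 2.9% were false. Few genes were changed in the simulation, while 31.4% were called in the data, which sets a looser cutoff on the unadjusted p. The simulated shares are therefore no estimate of what the real comparison recovered.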

Results

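Expression was measured in 6 libraries labelled RPMI-8226, a human multiple myeloma line, at 48 h. The 3 control libraries were compared with 3 libraries of cells treated with XYA1353, a compound whose activity against myeloma the study links to NF-kB signalling, a pathway of inducible transcription factors. The comparison asks which transcripts, NF-kB targets among them, differed after treatment. TPM values give no depth, so the depth behind each value is unknown. The number of named genes at 1 TPM or more was 13034 ± 144 (SD, n = 3) in control libraries and 13551 ± 172 (SD, n = 3) in XYA1353 libraries. The first principal component held 51.5% of the variance and separated the groups. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.965 to 0.981 within groups and 0.941 to 0.962 between groups.

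The libraries labelled RPMI-8226 held abundant erythroid transcripts and little or none of many plasma cell marker transcripts, in both groups. HBG2, a fetal globin gene (ENSG00000196565, GRCh38 chromosome 11, 5253190 to 5505605, minus strand), stood at 5689 ± 766 TPM in control and 5020 ± 2419 TPM in XYA1353 libraries (SD, n = 3). RHAG, a Rh complex glycoprotein of red cells (ENSG00000112077, chromosome 6, 49605158 to 49636884, minus strand), stood at 452 ± 8.94 and 413 ± 30.2 TPM, and GATA1, an erythroid transcription factor, at 163 ± 7.97 and 149 ± 22.7 TPM. HBG1 and HBG2, like HBA1 and HBA2, are near-identical copies, so the split between them is uncertain. In contrast, CD38, TNFRSF17, JCHAIN, IGLC2, IGLC3, IGHA1 and MAF, which mark plasma cells or myeloma, were listed at 0 in all 6 libraries. IRF4, a transcription factor on which plasma cells depend, reached at most 0.01 TPM, and SDC1, a plasma cell surface proteoglycan, at most 0.33 TPM. Of 40 erythroid genes listed after HBG2 had been seen, 33 had a mean of at least 10 TPM. Of 30 B lineage genes listed at the same time, none had, and 27 had a mean under 1 TPM. The highest was DERL3, at 3.65 TPM. Of the 25 plasma cell genes listed before any value was seen, by contrast, 7 had a mean of at least 10 TPM, SSR4 the highest at 343 TPM, and 15 had a mean under 1 TPM. Apart from that list, the genes of this paragraph were chosen after their values were seen.

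**Figure D1:**
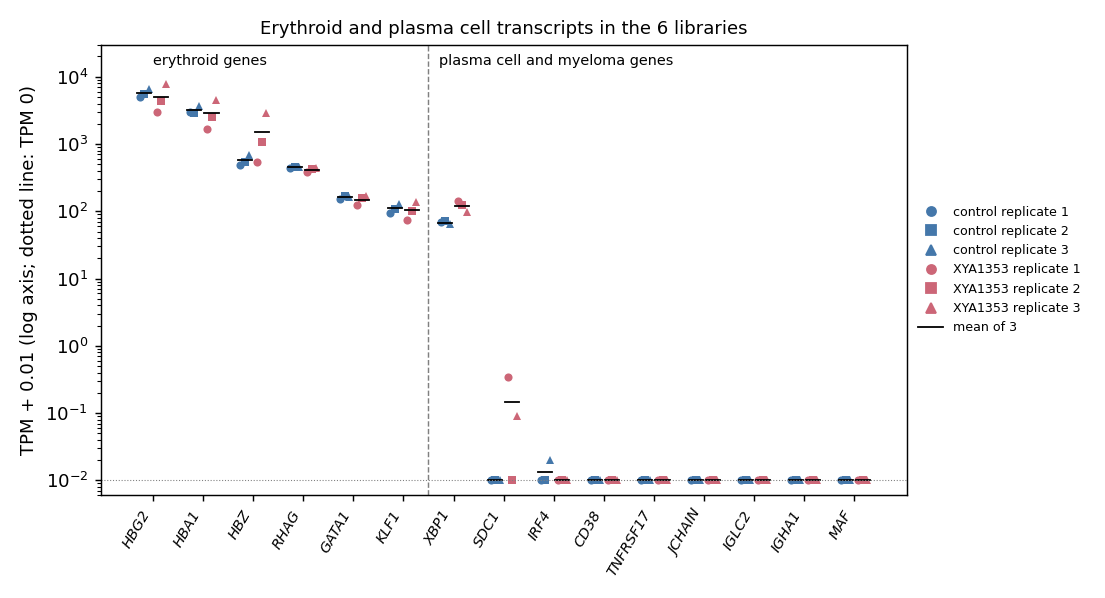
TPM plus 0.01 on a log axis for 6 erythroid genes (left) and 9 plasma cell and myeloma genes (right), a point per library and a bar at the mean of 3. The erythroid genes lay at high levels in all 6 libraries, and the genes from CD38 to MAF were listed at 0 in all 6.

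In the libraries labelled XYA1353, transcripts of NF-kB target genes, of the integrated stress response and of ribosomal proteins were higher than in controls. Transcripts of ribosome biogenesis factors, proteasome subunits and heat shock proteins were lower. Each of these 6 lists was called by camera at the preset correlation, with adjusted p = 0.484 with an estimated correlation. CXCL8, a neutrophil chemokine, showed the largest rise, from 1.34 ± 0.368 to 117 ± 72.8 TPM (SD, n = 3). THEM4, an acyl-CoA thioesterase gene, fell from 431 ± 31.9 to 114 ± 28.4 TPM.

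Of 13392 genes tested, 4210 (31.4%) changed, 2067 upward and 2143 downward, and 5738 passed an unadjusted p under 0.05. The groups did not overlap for 47.6% of genes, against 10% by chance. Changes of at least 1 on the log2 scale went mostly upward, with 512 genes higher and 86 lower. Of the 512, 319 had a control mean under 5 TPM. Among protein-coding genes 1746 rose and 2019 fell of 10845, and among genes of other types or not matched in the annotation 321 rose and 124 fell of 2547. The response was smaller in XYA1353 replicate 3. Over 797 genes called without that library by at least 1 on the log2 scale, its median change was 67.7% of that in the other 2 XYA1353 libraries, against 109.8% for replicate 1 and 105.8% for replicate 2 on genes chosen in the same way. The count was 2677 without XYA1353 replicate 2 and 1826 without both libraries numbered 1. It stood at 4510 without XYA1353 replicate 3.

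NF-kB target genes had the highest median fold change of the 22 lists tested. Of 33 tested members 26 rose, 2 fell and 5 were not called, with a median log2 fold change of 1.77, or 1.74 without TNF. The count adjusted over the list alone was 26 higher and 3 lower. CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716, plus strand) rose by 5.48 (SE 0.42, limma adjusted p = 0.00122). PLAU, the urokinase gene, rose by 4.12, RELB, an NF-kB subunit, by 3.70 and LTB, the lymphotoxin beta gene, by 3.24. With a pseudocount of 0.1 the rise of LTB was 5.51. ICAM1, an adhesion molecule, rose by 2.91 and TNFAIP3, a deubiquitinase that restrains NF-kB, by 2.88. TNF, chosen after its values were seen, was listed at 0 in every control library and at 5.78, 4.91 and 3.58 TPM in XYA1353 replicates 1, 2 and 3. The members that fell were STAT5A (log2 fold change -0.42), a cytokine-activated transcription factor, and PTPN1 (-0.34), a tyrosine phosphatase, both named after their values were seen. The camera adjusted p was 4.33e-10, but adjusted p = 0.484 with an estimated correlation. The mean log2 fold change of the list was 1.95 in XYA1353 replicate 1, 1.89 in replicate 2 and 1.30 in replicate 3.

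The NF-kB subunit genes differed in their response. NFKBIA, the inhibitor that NF-kB itself induces (ENSG00000100906, chromosome 14, 35401511 to 35404749, minus strand), rose from 12.9 ± 1.29 to 101 ± 32.3 TPM (SD, n = 3), a log2 fold change of 2.82 (SE 0.23, limma adjusted p = 0.00122). NFKB2 rose by 2.50 (adjusted p = 0.00151) and NFKB1 by 0.45 (adjusted p = 0.0134). The NFKB1 call was lost without XYA1353 replicate 2 (adjusted p = 0.052) and without control replicate 3 (adjusted p = 0.0505). RELA stood at 58.0 ± 3.64 and 58.4 ± 8.85 TPM (log2 fold change 0.00, SE 0.12, adjusted p = 0.997). REL stood at 2.96 ± 0.314 and 2.63 ± 0.361 TPM (-0.13, SE 0.16, adjusted p = 0.561). Of 26 tested genes of NF-kB pathway components, RELA, NFKBIB and NFKBID among them, 3 rose, 2 fell and 21 were not called, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.284). TRADD, a receptor adaptor, rose by 0.81 and TNFRSF1B, a TNF receptor gene, fell by 0.54. The TNFRSF1B call was lost without both libraries numbered 1 (limma adjusted p = 0.0613). IKBKG and CYLD, which also rose, and CHUK, which also fell, were named after their values were seen. The IKBKG and CYLD calls were lost without any 1 library other than XYA1353 replicate 3 (adjusted p from 0.054 to 0.135), the CHUK call without any 1 library other than XYA1353 replicate 1 (adjusted p from 0.0663 to 0.0976), and the CYLD call also with the replicate number as a block (adjusted p = 0.0859). Without any 1 library the number that rose was 1, except without XYA1353 replicate 3, where it was 7, and the number that fell was 1, except without XYA1353 replicate 1, where it was 2.

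**Figure D2:**
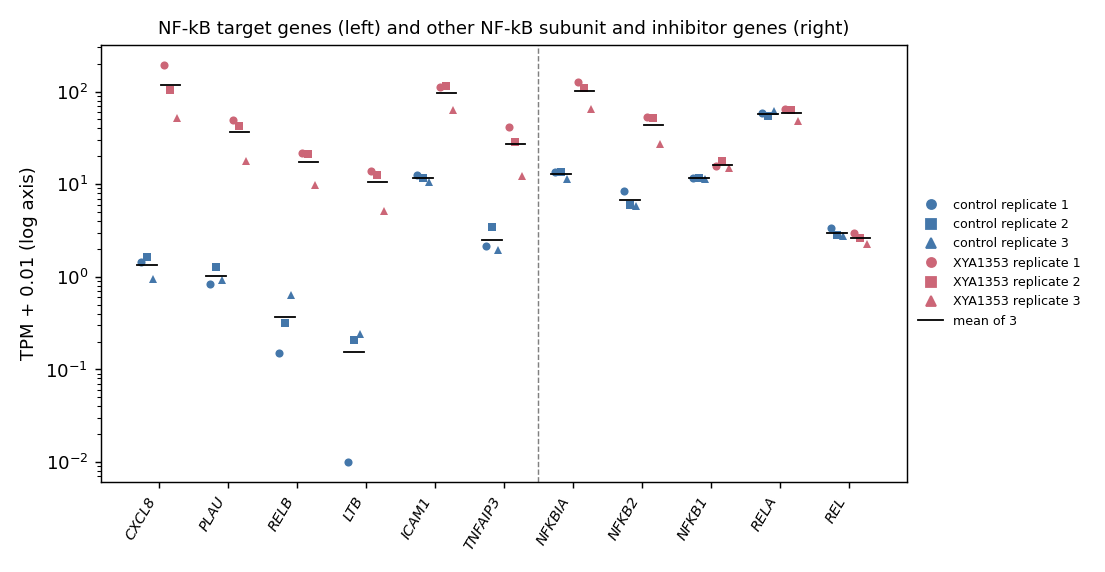
TPM plus 0.01 on a log axis for 6 NF-kB target genes (left) and 5 further NF-kB subunit and inhibitor genes (right), a point per library and a bar at the mean of 3. The 6 target genes, NFKBIA and NFKB2 were higher in each XYA1353 library than in each control library, while RELA and REL overlapped between groups.

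Genes of the integrated stress response, which ATF4 drives, rose almost throughout. Of 28 tested members 23 rose, 0 fell and 5 were not called, with 24 higher and 0 lower at an unadjusted p under 0.05. Adjusted over the list alone, 23 rose (camera adjusted p = 2.44e-10; adjusted p = 0.484 with an estimated correlation). DDIT3, which encodes the stress factor CHOP, rose from 20.7 ± 2.35 to 169 ± 61.8 TPM (SD, n = 3), and DDIT4, an inhibitor of mTORC1 signalling, from 94.3 ± 57.5 to 354 ± 51.9 TPM. The DDIT4 call was lost without XYA1353 replicate 2 (adjusted p = 0.0607). Of 29 unfolded protein response genes 11 rose, 1 fell and 17 were not called, and adjusted over the list alone 12 rose and 1 fell (camera adjusted p = 0.0116; adjusted p = 0.633 with an estimated correlation). HERPUD1, a factor in degradation of endoplasmic reticulum proteins, rose by 1.31 and EDEM1, of the same process, by 0.95. The member that fell was SSR1, a translocon-associated protein gene named after its values were seen. Without control replicate 1, 7 members rose, and without both libraries numbered 1, 4, with the EDEM1 call lost (limma adjusted p = 0.0655). The fry test, which asks whether members move one way, gave an adjusted p of 0.0944 for this list.

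Several p53 targets and cell death genes rose with these. Of 20 tested p53 target genes 9 rose, 1 fell and 10 were not called, and adjusted over the list alone 9 rose and 2 fell (camera adjusted p = 0.0116; adjusted p = 0.524 with an estimated correlation). GDF15, a stress-induced cytokine (ENSG00000130513, chromosome 19, 18374731 to 18389176, plus strand), rose from 101 ± 14.7 to 866 ± 91.6 TPM (SD, n = 3; limma adjusted p = 0.000121). CDKN1A, a cyclin-dependent kinase inhibitor, rose from 7.55 ± 1.29 to 56.4 ± 10.9 TPM. TRIAP1, named after its values were seen, fell. Without XYA1353 replicate 1, 2 members fell, with MDM2 called in addition (log2 fold change -0.33, limma adjusted p = 0.0377). MDM2, also named after its values were seen, was not called with all libraries. The median log2 fold change of the p53 list was 0.21. Of 25 apoptosis regulators 7 rose, 4 fell and 14 were not called, and adjusted over the list alone 9 rose and 5 fell (camera adjusted p = 0.137, or 0.0409 without XYA1353 replicate 3). BBC3, which encodes the cell death activator PUMA, rose by 2.37 and TNFRSF10B, a TRAIL receptor gene, by 1.98. Those that fell, named after their values were seen, were BID and CYCS, which act in mitochondrial apoptosis, TNFRSF10A, another TRAIL receptor gene, and XIAP, a caspase inhibitor. The XIAP call was lost with the replicate block (adjusted p = 0.0561) and without any 1 library other than XYA1353 replicate 2 (adjusted p from 0.0676 to 0.143), and the TNFRSF10A call without control replicate 1 (adjusted p = 0.0538). Without control replicate 1, 2 apoptosis regulators fell, and without XYA1353 replicate 3, 10 rose. Without both libraries numbered 1, 4 rose and 1 fell, and the TNFRSF10B call was lost (limma adjusted p = 0.0507).

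JUN rose among immediate early genes and SQSTM1 among oxidative stress genes. Of 17 AP-1 and immediate early genes 5 rose, 0 fell and 12 were not called, with 9 higher and 0 lower at an unadjusted p under 0.05, and adjusted over the list alone 5 rose. With the replicate number as a block 9 rose. The camera adjusted p was 0.00384, but adjusted p = 0.53 with an estimated correlation, and fry gave 0.0578, or 0.0486 with the block. JUN rose by 2.84 and MAFF by 1.11, both genes of basic leucine zipper factors. JUNB, JUND and DUSP5, a phosphatase gene, also rose and were named after their values were seen. The DUSP5 call was lost without XYA1353 replicate 1 or 2 or control replicate 1 (adjusted p from 0.0506 to 0.0712). Of 21 NRF2 oxidative stress genes 3 rose, 2 fell and 16 were not called, the same counts as adjusted over the list alone (camera adjusted p = 0.204, or 0.0111 without XYA1353 replicate 3). With the replicate block 7 rose and 3 fell, and without XYA1353 replicate 3 10 rose. Without any other single library 2 rose, and without XYA1353 replicate 2 or any 1 control library 1 fell. SQSTM1, an autophagy receptor gene, rose by 2.46 and OSGIN1, a gene induced by oxidative stress, by 1.35. The OSGIN1 call was lost without any 1 library other than XYA1353 replicate 3, with adjusted p from 0.0561 to 0.106. FTH1, of ferritin, rose and PRDX1, a peroxiredoxin gene, fell, both named after their values were seen.

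Interferon-stimulated genes were mostly at low levels, with 19 of 30 under 1 TPM. Of 11 tested members 6 rose, 1 fell and 4 were not called, the same counts as adjusted over the list alone (camera adjusted p = 0.0181; adjusted p = 0.524 with an estimated correlation). IFI35, an interferon-induced protein gene, rose by 0.82 and IFI16, a DNA sensor gene, by 0.73, while ISG15, a ubiquitin-like modifier named after its values were seen, fell. The list's call was lost without XYA1353 replicate 1 (adjusted p = 0.0522), with a mean of at least 5 TPM (adjusted p = 0.125), and without both libraries numbered 1 (adjusted p = 0.0531). Without both libraries numbered 1, 0 members rose and 1 fell. By contrast, 3, 2 and 3 members rose without XYA1353 replicate 1, XYA1353 replicate 2 and control replicate 1. The IFI35 call was lost without XYA1353 replicate 1 or 2 or control replicate 1 or 3 (adjusted p from 0.0528 to 0.0608), and the IFI16 call without XYA1353 replicate 2 (adjusted p = 0.0501).

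Genes of ribosome biogenesis fell while ribosomal protein genes rose. Of 29 tested MYC and ribosome biogenesis genes 1 rose, 27 fell and 1 was not called, the same counts as adjusted over the list alone, with a median log2 fold change of -0.70 (camera adjusted p = 4.27e-13; adjusted p = 0.484 with an estimated correlation). UTP20, a pre-ribosomal RNA processing factor, fell by 1.25 and NOP2, an RNA methyltransferase of the nucleolus, by 1.13. CDK4, a G1 kinase gene, rose, and MYC was not called (187 ± 66.2 and 173 ± 70.1 TPM, limma adjusted p = 0.817). Both were named after their values were seen. Of 75 cytosolic ribosomal protein genes 65 rose, 1 fell and 9 were not called, and adjusted over the list alone 69 rose and 1 fell. The median log2 fold change was 0.30 (camera adjusted p = 3.97e-20; adjusted p = 0.484 with an estimated correlation). RPL13A rose by 0.62 and RPS26 fell by 0.75. Many ribosomal protein genes have processed pseudogenes, so single values are uncertain. The share of TPM in ribosomal protein genes was 20.8 ± 0.38% in control and 25.99 ± 0.987% in XYA1353 libraries (SD, n = 3). Under quantile normalization 34 ribosomal protein genes rose and 4 fell, with no filter on low values 38 rose, and without both libraries numbered 1, 32 rose.

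Proteasome and heat shock genes were lower. Of 31 proteasome subunit genes 0 rose, 25 fell and 6 were not called, with 0 higher and 26 lower at an unadjusted p under 0.05. Adjusted over the list alone, 26 fell, and the median log2 fold change was -0.34 (camera adjusted p = 3.33e-11; adjusted p = 0.484 with an estimated correlation). Without both libraries numbered 1, 12 fell. PSMD12 fell from 101 ± 5.29 to 56.8 ± 5.66 TPM (SD, n = 3) and PSMD1 from 85.7 ± 0.30 to 52.3 ± 8.09 TPM, both of the regulatory particle. Of 20 heat shock response genes 0 rose, 13 fell and 7 were not called, with 1 higher and 15 lower at an unadjusted p under 0.05. Adjusted over the list alone, 1 rose and 13 fell (camera adjusted p = 2.31e-06; adjusted p = 0.484 with an estimated correlation). FKBP4, a co-chaperone of HSP90, fell by 1.04 and HSP90AA1, the inducible cytosolic HSP90, by 0.96.

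Among cell cycle genes most members were not called, and more fell than rose. Of 32 G2/M and mitosis genes 1 rose, 15 fell and 16 were not called, and adjusted over the list alone 1 rose and 20 fell (camera adjusted p = 5.93e-05; adjusted p = 0.484 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell by 0.77 and MKI67, a proliferation antigen gene, by 0.74, while CDC25C, a phosphatase that activates CDK1, rose and was named after its values were seen. Of 33 G1/S and DNA replication genes 2 rose, 10 fell and 21 were not called, and adjusted over the list alone 2 rose and 11 fell (camera adjusted p = 0.00113; adjusted p = 0.524 with an estimated correlation). MCM4, a subunit of the replicative helicase, fell by 0.73 and UNG, a uracil-DNA glycosylase gene, by 0.59. CDT1, a replication licensing factor, and E2F1, a transcription factor of S phase entry, rose and were named after their values were seen. Of 19 replication-dependent histone genes 1 rose, 2 fell and 16 were not called, and adjusted over the list alone 0 rose and 1 fell (camera adjusted p = 0.284). HIST1H2BC fell by 0.83 and HIST1H2AG rose by 0.39. HIST2H2AC, named after its values were seen, also fell.

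Several of these cell cycle counts and calls changed when a library was left out or a setting was changed. The number of G2/M genes that fell was 8 without control replicate 1 and 9 without control replicate 2, without XYA1353 replicate 2 or under quantile normalization. It was 4 without both libraries numbered 1 and 20 after rescaling without abundant classes. The G1/S list lost its call under quantile normalization (camera adjusted p = 0.064), and 16 of its members fell after rescaling without abundant classes, 15 without XYA1353 replicate 3 and 6 without both libraries numbered 1. The number of its members that rose was 1 without XYA1353 replicate 2 or any 1 control library and 0 without both libraries numbered 1. The E2F1 call was lost without any 1 library other than XYA1353 replicate 3 (adjusted p from 0.051 to 0.111). Over those fits its log2 fold change stayed at 0.26 to 0.36, against 0.31 with all libraries. The MCM4 call was lost without control replicate 1 (adjusted p = 0.0596) and with no filter on low values (adjusted p = 0.0588). Its log2 fold change was -0.44 without both libraries numbered 1. The HIST1H2AG call was lost without XYA1353 replicate 1 or any 1 control library (adjusted p from 0.0548 to 0.0893). The HIST2H2AC call was lost without XYA1353 replicate 1 or 2 or control replicate 3 (adjusted p from 0.112 to 0.126), where, as without control replicate 2, 1 histone gene fell. With the replicate block 2 histone genes rose and 4 fell, and without XYA1353 replicate 3 6 fell, with a camera adjusted p of 0.0208.

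Mitochondrial transcripts took a smaller share of the XYA1353 libraries, 10.6 ± 0.959% of TPM against 14.8 ± 0.261% in controls (SD, n = 3). Of 13 mitochondrially encoded mRNAs 1 rose, 7 fell and 5 were not called, and adjusted over the list alone 1 rose and 8 fell (camera adjusted p = 0.00332; adjusted p = 0.484 with an estimated correlation). MT-ATP6, of ATP synthase, fell by 0.79 and MT-CO3, of cytochrome c oxidase, by 0.76. MT-ATP6 overlaps MT-ATP8, so their split is uncertain. MT-ND4, of complex I, rose by 0.34 and was named after its values were seen, but under quantile normalization 0 of the 13 rose and 8 fell. Without control replicate 3, 2 of the 13 rose, MT-ND4L in addition (adjusted p = 0.00914), which overlaps MT-ND4 and so is uncertain. Of 48 nuclear oxidative phosphorylation genes 4 rose, 21 fell and 23 were not called, and adjusted over the list alone 4 rose and 22 fell (camera adjusted p = 0.000246; adjusted p = 0.524 with an estimated correlation). ATP5MC1, of ATP synthase, fell by 0.57 and NDUFA9, of complex I, by 0.54. NDUFB5, NDUFS8, COX5B and ATP5PD rose and were named after their values were seen. This list lost its call under quantile normalization (camera adjusted p = 0.137). The NDUFB5 call was lost without XYA1353 replicate 1 or 2 or control replicate 1 or 3 (adjusted p from 0.0794 to 0.119), and the NDUFS8 call without XYA1353 replicate 2 or any 1 control library (adjusted p from 0.0702 to 0.105). Without XYA1353 replicate 2, control replicate 1 or control replicate 3, 2 of its members rose. The number that fell was 14 without XYA1353 replicate 2 and 26 without XYA1353 replicate 3.

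Glycolysis and cholesterol synthesis genes moved in both directions. Of 29 hypoxia and glycolysis genes 8 rose, 12 fell and 9 were not called, and adjusted over the list alone 8 rose and 13 fell. Its median log2 fold change was -0.11 and its mean 0.08, while the test pointed down (camera adjusted p = 0.256). ENO2, an enolase gene, rose by 2.24 and VEGFA, an angiogenic growth factor gene, by 1.99. Without XYA1353 replicate 1 or 2, or control replicate 1 or 3, 5 members rose. Of 25 cholesterol synthesis genes 3 rose, 6 fell and 16 were not called, and adjusted over the list alone 3 rose and 7 fell (camera adjusted p = 0.0821). DHCR7, which makes cholesterol from its last precursor, fell by 0.68 and TM7SF2, a sterol reductase gene, rose by 0.66. SQLE and SREBF2, named after their values were seen, also rose. The TM7SF2 call was lost without control replicate 2 (adjusted p = 0.0575), and the SREBF2 call without XYA1353 replicate 2 or control replicate 1 or 2 (adjusted p from 0.0569 to 0.0632). The cholesterol list was called without XYA1353 replicate 1 (adjusted p = 0.00359) and without control replicate 3 (adjusted p = 0.0491). The number of its members that fell was 9 without XYA1353 replicate 1, 2 without XYA1353 replicate 2 or under quantile normalization and 3 without control replicate 2 or 3, and 1 rose without control replicate 2.

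**Figure D3:**
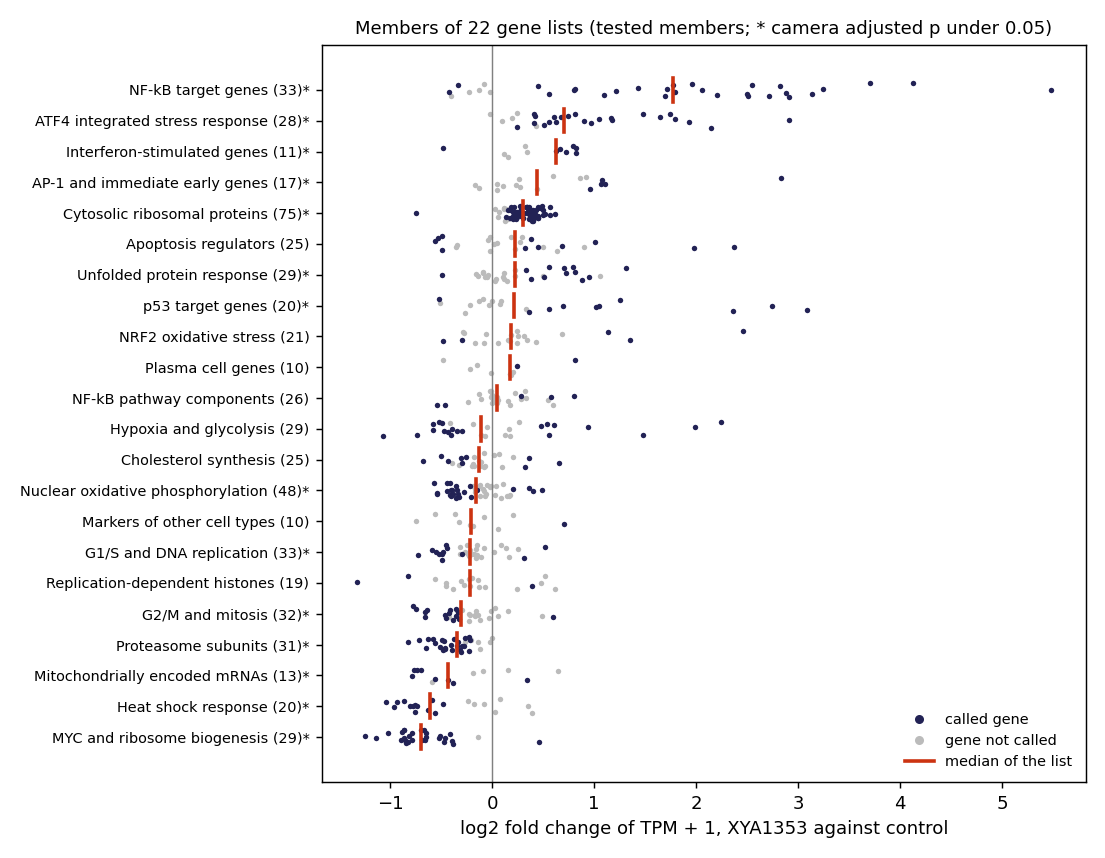
Log2 fold change of TPM plus 1 (x axis, XYA1353 against control) of each tested member of 22 gene lists (y axis, number tested in brackets), with called genes dark, other genes grey and a red bar at the median. The NF-kB target list has the highest median, 1.77, and the MYC and ribosome biogenesis list the lowest, -0.70.

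Among the largest rises after CXCL8 were those of PLAU, RELB, IL32 and BEX2. IL32, a cytokine gene, rose from 0.513 ± 0.166 to 19.8 ± 7.94 TPM (SD, n = 3) and BEX2 from 1.80 ± 0.954 to 32.9 ± 15.2 TPM. THEM4 (ENSG00000159445, chromosome 1, 151873584 to 151909808, minus strand) fell by 1.94 on the log2 scale (SE 0.16, adjusted p = 0.00122). CD3EAP, which encodes a subunit of RNA polymerase I, fell from 28.3 ± 3.97 to 8.99 ± 2.16 TPM. The U2 gene, for a spliceosomal RNA with near-identical copies elsewhere and so uncertain, fell by 2.22, and the genes AL031293.1, not matched in the annotation, and MRPS30-DT by 1.78 and 1.73, with MRPS30-DT antisense to its neighbour and so uncertain without strand. FABP5P7, a processed pseudogene whose reads cannot be told from its parent gene with certainty, fell by 2.54 (adjusted p = 0.0306). Its call was lost with the replicate number as a block (adjusted p = 0.0554) and without any 1 control library (adjusted p from 0.0567 to 0.0992). It was also lost with a pseudocount of 0.1 (adjusted p = 0.083), with no filter (0.102) and with eBayes without a trend (0.0508). The log2 fold change of FABP5P7 was -1.68 without XYA1353 replicate 1 and -1.32 without both libraries numbered 1.

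Lists for the labelled cell type and for other cell types gave few testable genes. Of 25 plasma cell genes 15 had a mean under 1 TPM, and of the 10 tested 2 rose, 0 fell and 8 were not called, with 4 higher and 0 lower at an unadjusted p under 0.05. Adjusted over the list alone, 2 rose (camera adjusted p = 0.246). XBP1, a transcription factor of secretory cells, rose from 68.0 ± 2.87 to 122 ± 22.5 TPM (SD, n = 3), and SSR4, a translocon-associated protein gene, from 314 ± 3.61 to 373 ± 13.8 TPM, neither of them specific to plasma cells. The SSR4 call was lost without XYA1353 replicate 2 (adjusted p = 0.0512), and without XYA1353 replicate 3, 3 members rose. Of 12 immunoglobulin genes 10 were listed at 0 in all libraries and none was tested. Of 28 markers of other cell types 18 had a mean under 1 TPM, and of the 10 tested 1 rose, 0 fell and 9 were not called, with 1 lower at an unadjusted p under 0.05, and adjusted over the list alone 1 rose (camera adjusted p = 0.733). Without XYA1353 replicate 3, 2 rose and 1 fell, and with the replicate block 1 rose and 1 fell. KRT19, an epithelial keratin gene, rose from 50.9 ± 6.43 to 83.3 ± 3.67 TPM. HBA1, an adult alpha globin gene in the same list, stood at 3157 ± 430 and 2931 ± 1474 TPM.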

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

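The tests on cell identity, on NF-kB target genes, on the mitochondrial share, on the unnamed loci and on other splits of the libraries were chosen only after the result was seen, while the test on mRNAs with a 5' terminal oligopyrimidine tract was written before its values were seen.

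The assembled loci without a gene name, which the comparison left out, were also tested. In a fit that kept them, 46 of 491 tested loci were called higher and 15 lower in XYA1353 libraries (limma, Benjamini-Hochberg adjusted), against 2067 higher and 2143 lower of 13392 named genes in the main fit, so a smaller share of the loci was called.

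All 6 libraries labelled RPMI-8226 carried abundant erythroid transcripts and little or none of many plasma cell marker transcripts. A mixed culture that still held many plasma cells would bring their abundant transcripts, but the highest mean of the 30 B lineage genes was 3.65 TPM (DERL3), and 10 of 12 immunoglobulin genes were listed at 0 in all libraries. The 7 of 25 plasma cell genes listed beforehand that had a mean of at least 10 TPM, such as SSR4 and XBP1, are not specific to plasma cells. An effect of the compound on cell identity is argued against by the control libraries, where the median of the 40 erythroid genes was 75.8 TPM. Libraries from a cell line other than the one labelled, of erythroid character, may account for the pattern, since 33 of the 40 erythroid genes had a mean of at least 10 TPM and 0 of the 30 B lineage genes had. Both lists were written after HBG2 had been seen, so these counts restate the pattern and are no separate test. No reference profile of any line was compared, and whether such a mix-up would lie in the cells, the RNA or the deposited table stays open.

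NF-kB target genes were higher in XYA1353 libraries. Scaling of the TPM values is argued against as the cause, since the lowest mean log2 fold change of the list under 3 other scalings was 1.649, against 1.71 as deposited. Cells of a type whose listed markers lie near 0 in the controls (means under 5 TPM) are argued against. Of those 22 markers the highest mean in XYA1353 libraries was 2.31 TPM (LYZ). LYZ was not called in the main fit, and was called lower with the replicate number as a block (limma adjusted p = 0.0413). Cells of a type whose listed markers are abundant in the controls stay open. Of 6 such markers 1 was called higher (KRT19, from 50.9 to 83.3 TPM), and the high control level would hide a small share. Without XYA1353 replicate 3 another, KRT8, was called higher (limma adjusted p = 0.0428). In that fit EPCAM, of the same list, was called lower (limma adjusted p = 0.0483). A response of the cultured cells to the compound may also underlie the rise, and a culture or handling difference that went with the groups was not tested.

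Ribosomal protein mRNAs were higher in XYA1353 libraries, with a median log2 fold change of 0.30. The lower share of mitochondrial transcripts in the TPM total is argued against as the whole cause, since rescaling without mitochondrial, immunoglobulin and ribosomal RNA genes left the median at 0.235. A rise of mRNAs with a 5' terminal oligopyrimidine tract in general may be a candidate explanation. The other mRNAs of that class had a median of 0.209, and 13 of 23 were called higher (camera p = 4.37e-05, but p = 0.168 with an estimated correlation). The size depends on the scaling, since the mean of the list was 0.13 under quantile normalization against 0.295 as deposited, and a difference in the growth of the cultures was not tested.

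Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many changed genes as the labels, namely the labelled split itself with 4210, and the highest of the others gave 3. The 10 splits are too few for a share under 0.05. Every other split also mixes control and XYA1353 libraries within a group, which puts any group difference into the spread. Their low counts are therefore no measure of the calls made without a group difference. Among the 3 other splits that also part all 3 same-numbered pairs of libraries the highest count was 1. Among the 6 that part fewer such pairs it was 3.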

How the results depend on the processing

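The fits without both libraries numbered 1 and with the unnamed loci kept were chosen only after the result was seen, and every other alternative here was planned. The count of 4210 changed genes (2067 higher, 2143 lower) lay between 3236 and 4441 under the pseudocount, filter, scaling, trend and unnamed-locus alternatives. A fold threshold of 1 on the log2 scale left 598 (512 higher, 86 lower), by its own construction. Leaving out 1 library gave 2677 to 4510 changed genes, 1238 to 2372 higher and 1439 to 2138 lower, the lowest without XYA1353 replicate 2 and the highest count without XYA1353 replicate 3. Without both libraries numbered 1 the counts were 1826, 819 and 1007, with fewer libraries in the fit. No scaling moved the share of calls that were higher by over 10 percentage points from 49.1%, the lowest being 39.6% after rescaling without abundant classes.

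With the replicate number as a block, 4286 genes changed, 2110 higher and 2176 lower, of which 3861 were among the 4210. In this fit camera called 14 lists, the same 14 as without the block, and fry called 9 lists against 12. With fry AP-1 was gained (adjusted p = 0.0486). The G1/S, G2/M, nuclear oxidative phosphorylation and interferon lists were lost (adjusted p from 0.0694 to 0.1). Of the 61 genes the rule takes FABP5P7 lost its call (adjusted p = 0.0554), and the block changed no other call among them.

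Camera called 14 of 22 lists at the preset correlation and 0 with an estimated correlation, where the NF-kB target list kept its mean log2 fold change of 1.712 and had an adjusted p of 0.484. The values tested are the same, but the test with an estimated correlation also has far fewer degrees of freedom. The loss of calls therefore does not measure correlation between genes alone. The adjusted p of that list ranged from 7.64e-12 to 2.45e-09 over the alternatives at the preset correlation, with a mean log2 fold change from 1.432 (no filter) to 2.215 (pseudocount 0.1). Over all lists and alternatives 366 calls stayed on their side of the threshold, 21 were lost and 8 were gained, and no called result changed sign. Fry did not call the unfolded protein response (adjusted p = 0.0944) or AP-1 (adjusted p = 0.0578) lists. The cholesterol synthesis list was called with no filter (adjusted p = 0.0117), after rescaling without abundant classes (0.0494) and without both libraries numbered 1 (0.00423). The causes were not tested. For the 61 genes 927 results stayed on their side and 46 lost the call. Of these, 11 were lost without both libraries numbered 1 and 6 with no filter, which adds tests. TPM carries no depth, so how far depth limits the low genes is unknown.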

Other observations

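The erythroid, megakaryocyte and B lineage lists and the replicate comparison of MYC were chosen only after the result was seen.

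Erythroid genes rose in XYA1353 libraries at a share not far from that of all genes, and the globin share did not shift beyond its spread. Of 37 tested erythroid genes 7 rose, 0 fell and 30 were not called, against 2067 higher and 2143 lower of 13392 genes. At an unadjusted p under 0.05, 9 were higher and 2 lower, and with the replicate number as a block 11 rose and 2 fell. The list as a whole was not called (camera p = 0.214; p = 0.784 with an estimated correlation). ALAS2, the first enzyme of heme synthesis in erythroid cells, rose from 6.22 ± 0.819 to 54.3 ± 21.2 TPM (SD, n = 3; limma adjusted p = 0.00132). GYPC, a glycophorin, rose from 324 ± 17.8 to 495 ± 37.5 TPM. ALAS2 and GYPC were named after their values were seen. The share of TPM in globin genes was 1.05 ± 0.131% in control libraries and 0.58, 0.91 and 1.70% in XYA1353 replicates 1, 2 and 3.

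MYC was lower in both libraries numbered 1 than in the other 4. It stood at 110, 228 and 222 TPM in control replicates 1, 2 and 3 and at 91.8, 210 and 216 TPM in XYA1353 replicates 1, 2 and 3, with a limma adjusted p of 0.817 for the comparison of groups and 0.168 with the replicate number as a block.

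Of 5 tested megakaryocyte genes and 3 tested B lineage genes limma called 0, with 1 megakaryocyte gene and 0 B lineage genes at an unadjusted p under 0.05. With the replicate number as a block 1 megakaryocyte gene was called higher. GP1BB, a platelet glycoprotein gene, was the highest megakaryocyte gene, at 67.5 ± 12.5 TPM in control and 120 ± 56.6 TPM in XYA1353 libraries (SD, n = 3).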
